A study of Mus musculus with 21 samples.

How the data were processed

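Transcript levels were measured by RNA sequencing in 21 libraries of CD11b+ peritoneal macrophages from C57BL/6 mice. The labels name 3 genotypes: wild type, Lum-/- (lumican knockout) and Bgn-/- (biglycan knockout). Per the labels' protocols, cells were flushed from unelicited peritoneal cavities (mice n = 10), selected for CD11b and plated overnight. LPS, a ligand of TLR4, was given at 100 ng/mL and CpG DNA, a ligand of TLR9, at 1 µM, each for 6 h. Recombinant lumican or biglycan was given at 10 µg/mL, 1 h before the stimulus. The labels state no dose or time for the 4 libraries given protein alone. Each combination of genotype, protein and stimulus has 1 library, and no label ties a well to an animal, so a genotype and its cell preparation are confounded. Per the labels, libraries came from a stranded TruSeq kit and an Illumina HiSeq instrument.

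Per the submitters' processing notes, the authors used bcl2fastq 1.8.4 and kallisto 0.44.0 with the build GRCm38. The 1 deposited table holds TPM (each transcript's share of its library) per transcript, normalized within each library by the authors, and every library sums to 1000000. The table names 89562 transcripts, and a gene for 82788 of them. Of the other 6774, 5424 were matched by transcript ID to GENCODE vM21, and 1350 without a gene were left out, at 5350.5 to 7548 TPM per library. TPM was summed to 23570 genes, and coordinates are 1-based, from GRCm38.

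The files give no counts, so sequencing depth is not stated. It was estimated from the spacing of low TPM values times length over 3704 coding genes with a single transcript of at least 1000 bases, with an assumed fragment length of 200 bases. Between 70.3% and 84.1% of low values lay within 0.2 of a whole read, against 40% if they were evenly spread. The step was set from the lowest of these same values, which by itself places values near a whole read. The step gave 2.33 M reads in the untreated library labelled Lum-/- and 2.31 M in the biglycan-alone library labelled Bgn-/-, against 13.4 to 21.3 M in the other 19. For every pair of libraries, the median chi-square of recovered reads per gene was divided by its value under sampling alone, over genes with at least 40 reads in the pair.

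Genes with a mean of at least 1 TPM were tested (11774) with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with lmFit, eBayes with a trend, two-sided tests and a Benjamini-Hochberg adjusted p under 0.05. An additive fit of genotype and the 9 treatments, with 10 residual degrees of freedom, gave the stimulus, genotype and protein comparisons. Fits with a genotype-by-stimulus or a genotype-by-protein term, with 6 or 8 residual degrees of freedom, gave the 6 comparisons of responses. The repeats are the same treatment in other genotypes, or the same genotype under other treatments. The spread behind the p-values thus holds well noise and any genotype-by-treatment difference that the fit leaves out, not the spread between animals. A real difference of that kind widens it. Standard errors (±) are from the same fits.

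Gene lists (29, of which 10 hold markers of cell types) were fixed with the tests, the named-gene rule and the main alternatives before the data were examined. For each comparison, 22 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. A further 5 lists have fewer tested genes, and 2 have none. Counts of list members are given over all genes tested and adjusted over the list alone. For single libraries, a list's median log2 difference was compared with 10000 random lists of the same size matched on mean expression in 20 bins, with no p-value. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 did the rest.

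Named genes follow a rule. Lum, Bgn, Tlr4, Tlr9 and Cd14 are always named. Against untreated, the 12 called genes with the largest rise and the 8 with the largest fall are named, with at least 10 TPM in the higher group and the same sign in all 3 genotypes, and 8 each way for LPS against CpG. Genotype comparisons name 8 each way, with at least 5 TPM and the same sign in all 6 matched treatments. Protein and response comparisons name up to 5 each way. From each list, the first 4 measured members and the 3 with the largest absolute change are eligible. Gene models without a proper symbol are counted but not named.

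Alternatives were pseudocounts of 0.1 and 5, a mean of at least 5 TPM, no filter, median-of-ratios scaling, quantile normalization, the most abundant transcript per gene, robust eBayes, no genotype block and only the libraries compared. Single libraries, all libraries of a stimulus or all libraries of a genotype were also left out in turn. Added after the data were seen were coding genes only, a mast cell score as a covariate, the mean over protein levels, list tests after scaling, and fits without 2 libraries (untreated labelled Lum-/- and biglycan alone labelled Bgn-/-) or without 3 (the wild-type untreated library as well). The single-library lists of protein alone were added then too.

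The fits were tested on simulated data, 11774 genes with 200 changed by a log2 of 1 or 2. Of 100 genes changed by 1, the stimulus comparisons recovered 80 to 84, the genotype comparisons 94, the protein comparisons 90, protein with stimulus 65 to 79, and the comparisons of responses 39 to 54. Of 100 changed by 2, the comparisons of responses recovered 77 to 93 and the rest 94 to 98. The simulated noise was independent between genes and, for each gene, equal in all libraries. Libraries of low depth, correlated genes and a shift of most genes were thus not simulated, and recovery in the data may differ. The depth estimate returned 2, 5 and 15 M reads where as many were drawn. The same fragment length was used to draw and to recover the reads, so that assumption was not checked.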

Results

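The series holds 21 libraries of CD11b+ peritoneal macrophages. Wild type has 9 libraries, and the labels Lum-/- and Bgn-/- have 6 each. Lumican and biglycan are small leucine-rich proteoglycans of the extracellular matrix. The design asks how each protein, its gene's loss and its addition alter the response to LPS and CpG. Wild-type cells received no protein, lumican or biglycan, each with no stimulus, LPS or CpG. Cells labelled Lum-/- received no protein or lumican, and cells labelled Bgn-/- no protein or biglycan, with the same stimuli. No group has a replicate, so single-library values below carry no replicate check. Libraries held 40231 to 59621 transcripts above 0, and estimated depth was 2.31 to 21.3 M reads. Saa3, an acute-phase serum amyloid gene, was the most abundant gene in every library, at 49083 to 125656 TPM.

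The targeted genes were read first, as a check of the labels. Lum (chromosome 10, 97565128 to 97572703) was measured in every library labelled Lum-/-, at 0.823 TPM untreated, 14.1 with LPS, 2.88 with CpG, 1.17 with lumican, 12.0 with lumican and LPS and 3.93 with lumican and CpG. In wild type, Lum was at 0 TPM untreated, 1.40 with LPS, 0.273 with CpG, 0.228 with lumican, 1.24 with lumican and LPS, 0.324 with lumican and CpG, 0.193 with biglycan, 0.718 with biglycan and LPS and 0.354 with biglycan and CpG. In the libraries labelled Bgn-/-, Lum was at 0.0404 TPM untreated, 0.105 with LPS, 0.0334 with CpG, 0.134 with biglycan and LPS, 0 with biglycan and CpG, but 1.10 with biglycan alone. Bgn (chromosome X, 73483602 to 73495933) was measured in 5 of the 6 libraries labelled Bgn-/-, at 0.948 TPM untreated, 0.758 with LPS, 3.49 with CpG, 1.18 with biglycan and LPS and 3.03 with biglycan and CpG, and at 0 with biglycan alone. In wild type, Bgn was at 0.796 TPM untreated, 0.330 with LPS, 0.961 with CpG, 0.442 with lumican, 0.459 with lumican and LPS, 1.52 with lumican and CpG, 1.03 with biglycan, 0.327 with biglycan and LPS and 0.542 with biglycan and CpG. In the libraries labelled Lum-/-, Bgn was at 1.72 TPM untreated, 0.0322 with LPS, 0.0325 with CpG, 0.263 with lumican and 0 with lumican and either stimulus. Both targeted genes therefore go against the knockout labels, so directions drawn from them below are those of the libraries as labelled.

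The untreated library labelled Lum-/- and the biglycan-alone library labelled Bgn-/- differed by less than sampling noise. Their noise ratio was 0.1895 over 8944 genes, where simulated draws from 1 library gave 0.8225 to 0.925. The other 209 pairs had ratios of at least 1.81, with a median of 16.8. Both libraries held high Arg1, the arginase of alternatively activated macrophages, at 688 and 601 TPM, against at most 67.2 elsewhere. The wild-type untreated library also stood apart, with the mast cell proteases Cma1 at 1.03 TPM and Mcpt4 at 0.462, against at least 20.5 and 10.9 in the other 8 wild-type libraries. These 3 libraries are 2 of the 3 untreated ones and the only biglycan-alone library labelled Bgn-/-.

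**Figure D1:**
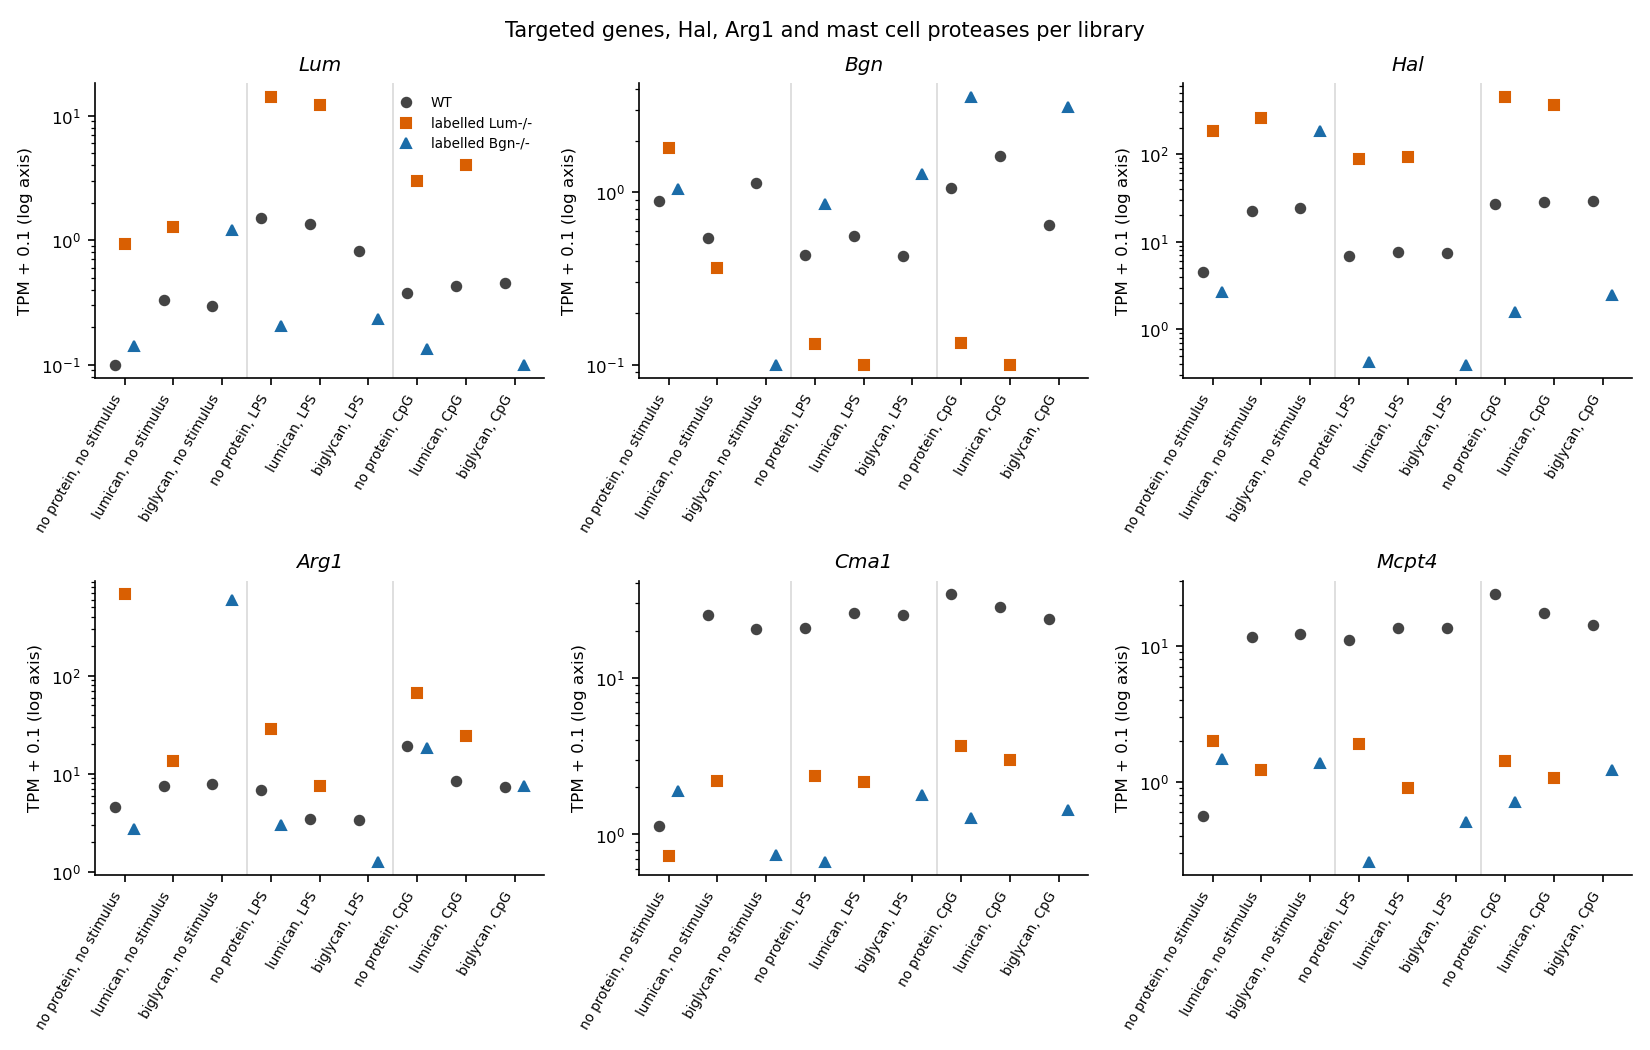
TPM + 0.1 (log axis) of Lum, Bgn, Hal, Arg1, Cma1 and Mcpt4 in each of the 21 libraries by treatment, with a symbol per genotype label and no replicates. Lum reaches 14.1 TPM under the label Lum-/-, Hal is high in every library of that label and in the biglycan-alone library labelled Bgn-/-, and Cma1 and Mcpt4 are low in the wild-type untreated library.

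LPS turned on a strong inflammatory and interferon program in all 3 genotypes. The cytokine gene Il6 rose by 9.37 ± 0.44 on the log2 scale, from a mean of 4.64 to 3276 TPM, the granulocyte factor gene Csf3 by 8.62 ± 0.31 and the chemokine gene Cxcl10 by 8.09 ± 0.36 (3 genotypes, limma adjusted p of at most 7.86e-10). The monocyte chemokine genes Ccl7 and Ccl2 rose by 8.03 and 7.50, Ccl4 by 7.36 and Csf2, a growth factor gene of myeloid cells, by 7.68. Ch25h, which makes 25-hydroxycholesterol, rose by 7.48, Ptgs2, a prostaglandin synthase gene, by 7.11, Il1b by 6.94, U90926 by 6.91 and the matrix protease gene Mmp3 by 6.80. All 25 measured inflammatory cytokine and chemokine genes rose, also when adjusted over the list alone, with a median of 5.41. For this list, camera gave adjusted p = 1.35e-33, and adjusted p = 0.0133 with an estimated correlation. Tnf rose by 4.85 ± 0.29 and Il12b by 4.88 ± 0.24. All 39 measured interferon-stimulated genes rose, also adjusted over the list alone, with a median of 3.11, among them Ifit1 by 4.66, Isg15 by 4.59, Rsad2 by 6.03, which codes for the antiviral protein viperin, and Irf7 by 3.12. The list's camera test gave adjusted p = 2.18e-33, but adjusted p = 0.145 with an estimated correlation.

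The largest falls named by the rule include receptor genes of immune cells. Cd300lb and Cd300a, receptors of the CD300 family, changed by -4.98 and -4.47, and Vsir, which codes for the checkpoint protein VISTA, by -4.82. The beta-arrestin gene Arrb1 changed by -4.58, the scaffold gene Slc9a3r2 by -4.44, Abi3 by -4.43, the kinesin light chain gene Klc4 by -4.26 and the glycosidase gene Engase by -4.26, each in all 3 genotypes. Of 20 NF-kB feedback genes and subunits, 15 rose and 0 fell, also adjusted over the list alone, and 20 rose after scaling. Camera gave the list adjusted p = 3.81e-17, and adjusted p = 0.0248 with an estimated correlation. The inhibitors Nfkbia and Tnfaip3 rose by 1.85 and 3.03, and Socs1 and Socs3, which restrain cytokine signalling, by 3.41 and 3.17. Of 17 genes of the unfolded protein response, 12 rose and 2 fell, also adjusted over the list alone, and 15 rose and 0 fell after scaling. As a set, they had a camera adjusted p = 2.86e-09, and adjusted p = 0.0248 with an estimated correlation. They include the chaperone gene Hspa5 (1.48), Atf4 (1.51) and its targets Chac1 (3.39), Asns (3.06) and Trib3 (2.69). Of 9 heat shock genes, 5 rose and 4 fell (after scaling 8 and 0), with Hspa1a up by 1.55. Taken as a list, they had a camera adjusted p = 0.00338, but adjusted p = 0.195 with an estimated correlation. The co-receptor gene Cd14 rose by 1.75 ± 0.13 and Tlr9 by 0.62 ± 0.25 (2 of 3 genotypes, limma adjusted p = 0.0354), whereas Tlr4 was 0.29 ± 0.14 (limma adjusted p = 0.0756). Lum itself rose by 1.47 ± 0.45 (limma adjusted p = 0.00881, 3 of 3 genotypes), and Bgn, with a mean under 1 TPM, was not tested.

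Further lists split in direction after LPS, and scaling moved many of them. Of 26 TLR receptors and adaptors, 8 rose and 12 fell (after scaling 17 and 7), Myd88 up by 0.97 and Tlr8 and Tlr13 down at -2.15 and -2.10. Camera weighs a list against all other genes, and this list had adjusted p = 0.021, but adjusted p = 0.283 with an estimated correlation. Its median after scaling was 0.74, against 0.01 for all genes. Of 19 antigen presentation genes, 9 rose and 6 fell (after scaling 15 and 2), with the co-stimulatory genes Cd40 and Cd274 up by 3.66 and 2.33. For this list, camera gave adjusted p = 2.04e-05, but adjusted p = 0.201 with an estimated correlation. Of 14 proteoglycan and matrix genes, 6 rose and 4 fell (after scaling 9 and 2), with the collagenase gene Mmp13 up by 4.74, the syndecan gene Sdc4 by 2.92 and decorin (Dcn) by 1.23. The list's camera test gave adjusted p = 0.000304, but adjusted p = 0.145 with an estimated correlation. Of 30 endocytic and lysosomal genes, 4 rose and 23 fell (after scaling 13 and 11), with Tfeb, a regulator of lysosome genes, down at -3.07 and Atp6v0d2 at -3.43. Of 21 scavenger and phagocytic receptors, 5 rose and 13 fell (after scaling 8 and 6), Scarb1 and Cd36 down at -2.19 and -1.93. Of 23 cholesterol synthesis genes, 4 rose and 10 fell (after scaling 14 and 5), with Dhcr7 down at -3.10. Of 11 cholesterol efflux and LXR target genes, 0 rose and 10 fell (after scaling 3 and 2), and of 24 oxidative phosphorylation genes, 1 rose and 23 fell (after scaling 9 and 9; camera adjusted p = 0.021, but adjusted p = 0.449 with an estimated correlation). Of 18 glycolysis genes, 5 rose and 10 fell (after scaling 8 and 6), the regulator Pfkfb3 up by 1.73 and Tpi1 down at -2.26. Of 14 oxidative stress genes, 3 rose and 6 fell (after scaling 9 and 3), of 26 cell cycle genes, 2 rose and 12 fell (after scaling 8 and 5), and of 10 alternative activation genes, 3 rose and 4 fell (3 and 6 adjusted over the list alone, and 3 and 1 after scaling). Except where stated, counts adjusted over the list alone were the same, and the camera test of these lists did not pass. No type I interferon gene reached a mean of 1 TPM, so that list was not tested.

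In all, limma called 9513 of 11774 genes after LPS, 1385 up and 8128 down, and 719 of those up and 4623 of those down changed over 2-fold. The median of all genes was -0.80, and after median-of-ratios scaling it was 0.01, with 4100 genes up and 3954 down, so falls smaller than this shift depend on the scaling.

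**Figure D2:**
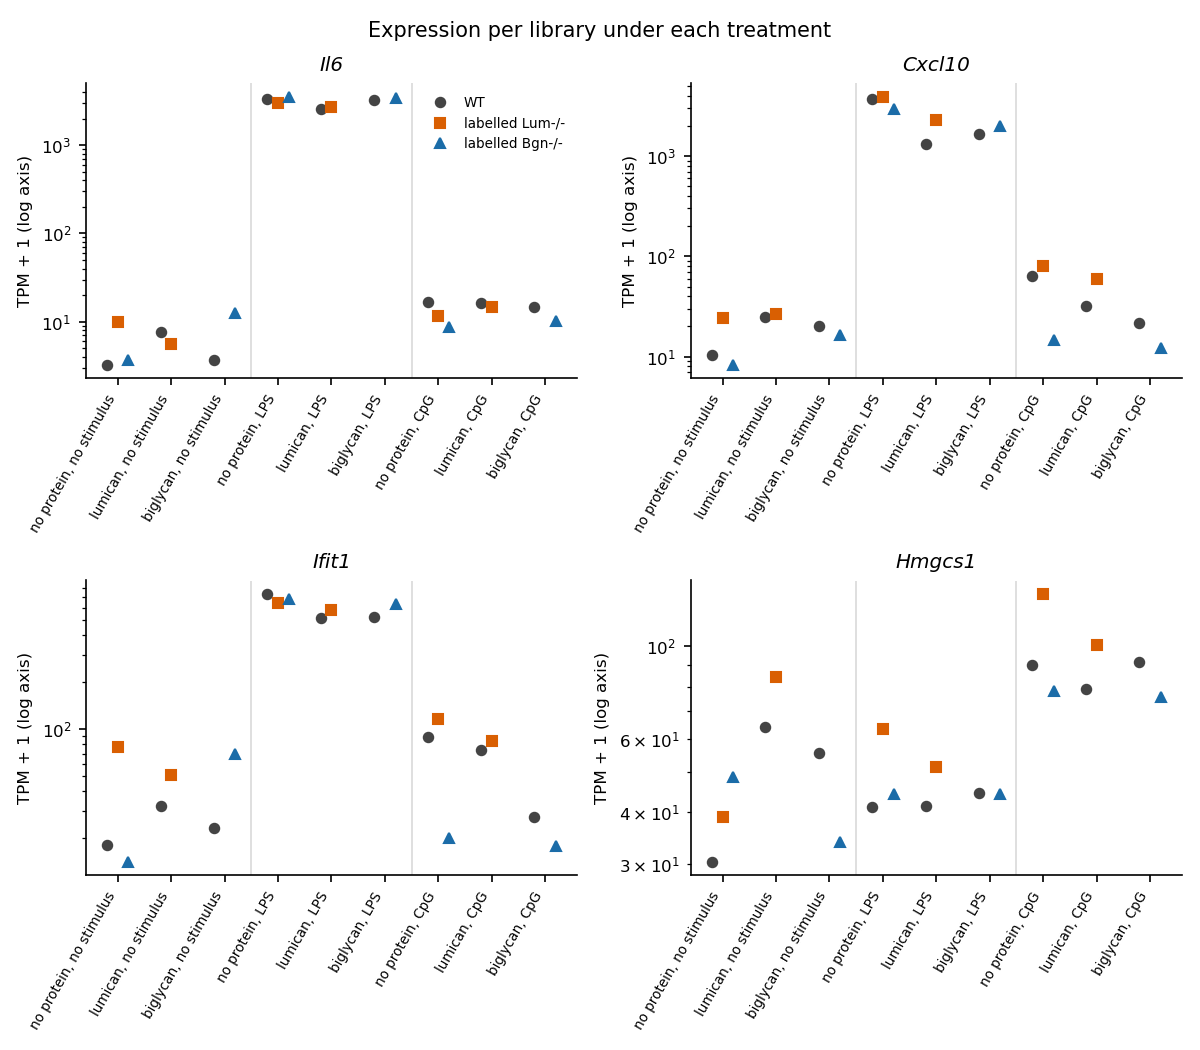
TPM + 1 (log axis) of Il6, Cxcl10, Ifit1 and Hmgcs1 in each of the 21 libraries by treatment, with a symbol per genotype label and no replicates. Il6 lies between 2542 and 3515 TPM in every LPS library and at most at 15.8 in every other.

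CpG gave a smaller response, in which cholesterol synthesis and cell cycle genes had the highest medians of the pathway lists. Of 23 cholesterol synthesis genes, 21 rose and 0 fell, also adjusted over the list alone and after scaling, with a median of 1.16. Camera gave the list adjusted p = 3.61e-20, but adjusted p = 0.221 with an estimated correlation. Hmgcs1 rose by 1.35 ± 0.19, Sqle by 1.46 ± 0.15 and Idi1 by 1.76 ± 0.19, each in all 3 genotypes. Of 26 cell cycle genes, 15 rose and 0 fell (18 and 1 adjusted over the list alone, and 16 and 0 after scaling), with a median of 0.70 and with Top2a up by 1.61 ± 0.25, Mcm5 by 1.82 ± 0.28 and Rrm2 by 1.76 ± 0.20. As a set, they had a camera adjusted p = 6.86e-11, but adjusted p = 0.221 with an estimated correlation. Among single genes, Ch25h rose by 3.45 ± 0.56, the cyclin gene Ccnd2 by 3.29 ± 0.29 and the nucleotide kinase gene Uck2 by 3.11 ± 0.15 (limma adjusted p of at most 0.00125).

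The immunoglobulin gene Ighg2b rose by 3.14, the metallothionein gene Mt2 by 2.97, Cdca7 by 2.92, the phosphatase gene Alpl by 2.68, the chemokine gene Ccl22 by 2.43 and the anti-inflammatory cytokine gene Il10 by 2.39. Chac1, which degrades glutathione, rose by 2.21, the amino acid transporter gene Slc7a5 by 2.17 and Ifi205 by 2.11. Engase changed by -2.23, the inhibitory lectin gene Siglecg by -2.20, Plac8 by -2.07, and Man2a2 by -1.84. Abca9, the peroxisomal transporter gene Abcd2 and the sterol hydroxylase gene Cyp27a1 fell too, and Tifab changed by -1.77. Of 25 inflammatory cytokine and chemokine genes, 10 rose and 0 fell (11 and 0 adjusted over the list alone, and 10 and 0 after scaling), with Tnf up by 1.13 ± 0.29 and Nos2 by 1.71 ± 0.44. Taken as a list, they had a camera adjusted p = 1.25e-07, but adjusted p = 0.221 with an estimated correlation. Il6 was 1.28 ± 0.44 (limma adjusted p = 0.0596, higher in 3 of 3 genotypes). All 39 interferon-stimulated genes were higher, with a median of 0.68, but 5 passed (3 adjusted over the list alone, and 6 after scaling), among them Cxcl10 at 1.71 ± 0.36. Tested together with camera, they had adjusted p = 4.04e-07, but adjusted p = 0.521 with an estimated correlation. Of 20 NF-kB genes, 9 rose (12 adjusted over the list alone, and 10 after scaling), with Nfkbiz up by 1.02. For this list, camera gave adjusted p = 1.06e-07, but adjusted p = 0.221 with an estimated correlation. Of 17 unfolded protein response genes, 5 rose (6 adjusted over the list alone, and also 6 after scaling), with Atf4 up by 1.03 and Asns by 2.09. The list's camera test gave adjusted p = 0.00124, but adjusted p = 0.221 with an estimated correlation.

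Endocytic and lysosomal genes leaned down, with 1 up and 12 down of 30 (3 and 15 adjusted over the list alone, and 2 and 8 after scaling), Lgmn down at -0.80. Camera gave the list adjusted p = 0.00663, but adjusted p = 0.506 with an estimated correlation. Oxidative phosphorylation genes had 0 up and 4 down of 24 (0 and 6 adjusted over the list alone, and 0 and 1 after scaling; camera adjusted p = 0.0416, but adjusted p = 0.521 with an estimated correlation). Proteoglycan and matrix genes had 6 up and 1 down of 14, also adjusted over the list alone, with Tgfbi up by 1.79. As a set, they had a camera adjusted p = 0.00709, but adjusted p = 0.32 with an estimated correlation. Glycolysis genes had 3 up and 1 down of 18, also adjusted over the list alone (4 and 0 after scaling), with the glucose transporter gene Slc2a1 up by 0.82. Taken as a list, they had a camera adjusted p = 0.035, but adjusted p = 0.521 with an estimated correlation. Lists whose camera test did not pass were TLR receptors (4 up and 7 down; 5 and 10 adjusted over the list alone), scavenger receptors (3 and 3), antigen presentation (1 and 4), LXR targets (1 and 3; 3 and 4 adjusted over the list alone), oxidative stress (1 and 4; 3 and 4 adjusted over the list alone), heat shock (2 and 0) and alternative activation (1 and 0; 0 and 0 adjusted over the list alone). After scaling, TLR receptors had 4 up and 6 down, scavenger receptors 3 and 2, antigen presentation 2 and 3, LXR targets 2 and 2, and oxidative stress 2 and 2. Lum was 0.48 ± 0.45 (limma adjusted p = 0.495), Tlr4 -0.09 ± 0.14, Tlr9 0.41 ± 0.25 and Cd14 0.16 ± 0.13, and none of these passed. In all, limma called 2262 genes, 836 up and 1426 down, and 1064 up and 984 down after scaling. Leaving out all 9 wild-type libraries gave 0 genes in limma, with 2 residual degrees of freedom left. Leaving out all 6 libraries labelled Lum-/- gave 483, and all 6 labelled Bgn-/- 1776, with 5 residual degrees of freedom each. With all libraries, 3978 genes had an unadjusted p under 0.05. Without the 3 libraries that stand apart, 926 genes were called, and a mean over protein levels without them gave 4466.

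**Figure D3:**
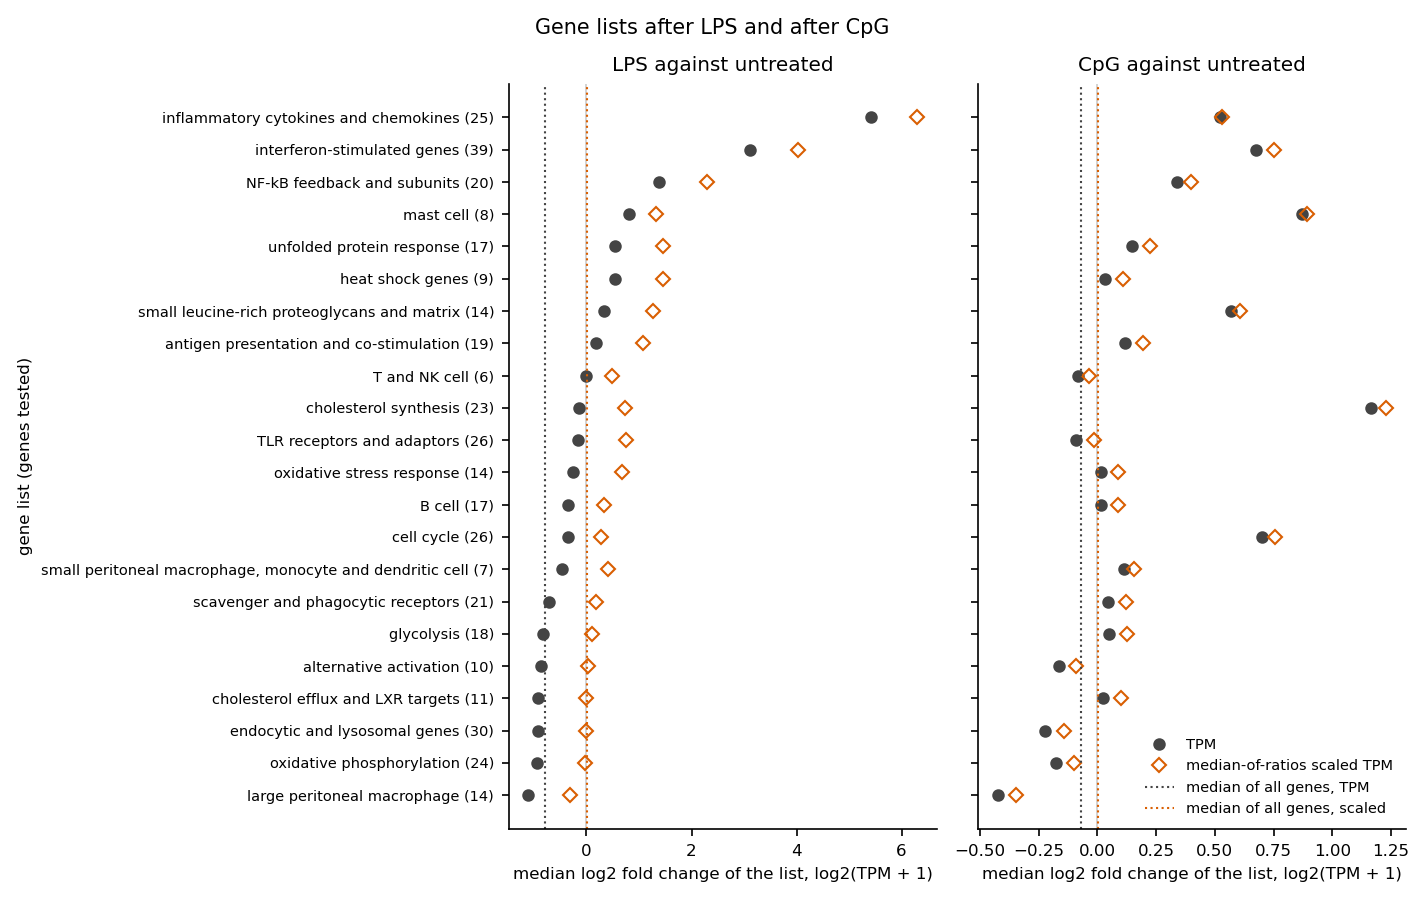
Median log2 fold change of each gene list with at least 5 tested genes after LPS (left) and CpG (right), for TPM (circles) and scaled TPM (diamonds), with dotted lines at the median of all genes. Cytokines lead after LPS (5.41) and cholesterol synthesis after CpG (1.16).

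LPS and CpG differed most in cytokine and chemokine genes. Il6 was higher with LPS than with CpG by 8.09 ± 0.44, Csf3 by 7.60 ± 0.31, Ccl7 by 7.51 ± 0.89 and Csf2 by 7.35 ± 0.25 (3 of 3 genotypes, limma adjusted p of at most 4.25e-06). Ccl2 was higher by 7.27, U90926 by 6.84, Mmp3 by 6.70 and Cxcl10 by 6.37. Lower with LPS were Cd300lb (-4.33), Arrb1 (-4.16), the matrix protein gene Tgfbi (-3.88), the peroxidase gene Gpx1 (-3.83), the desaturase gene Scd2 (-3.79), the inhibitory receptor gene Lair1 (-3.74), Vsir (-3.73) and Abi3 (-3.70). Cytokines were higher in 23 and lower in 1 of 25, also adjusted over the list alone. Tested together with camera, they had adjusted p = 6.42e-35, and adjusted p = 0.0115 with an estimated correlation. Interferon-stimulated genes were higher in 39 of 39, also adjusted over the list alone. For this list, camera gave adjusted p = 1.06e-34, but adjusted p = 0.136 with an estimated correlation. Cholesterol synthesis genes were higher in 0 and lower in 22 of 23, also adjusted over the list alone (after scaling 0 and 13), with Dhcr7 at -3.16 and Sqle at -1.71. The list's camera test gave adjusted p = 0.0194, but adjusted p = 0.617 with an estimated correlation. Cell cycle genes were higher in 1 and lower in 21 of 26, also adjusted over the list alone (after scaling 2 and 14), with the replication genes Mcm2 at -2.47 and Mcm3 at -2.34, but most tested genes were lower and the list did not pass (camera adjusted p = 0.478, and adjusted p = 0.865 with an estimated correlation). NF-kB genes were higher in 14 and lower in 2 of 20 (after scaling 19 and 0; adjusted p = 0.0371 with an estimated correlation), and unfolded protein response genes in 11 and 2 of 17 (after scaling 15 and 0; adjusted p = 0.0371 with an estimated correlation). Cd14 was higher by 1.59 ± 0.13 and Tlr4 by 0.38 ± 0.14 (limma adjusted p = 0.0254), and Lum was 0.99 ± 0.45 (limma adjusted p = 0.0596). In all, limma called 9359 genes, 1164 up and 8195 down, with a median of all genes of -0.75 that scaling moved to -0.02, with 3743 up and 3746 down.

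Libraries labelled Lum-/- differed from wild type most in a single gene, and sterol genes leaned up and antioxidant genes down, though neither list passed camera with an estimated correlation. Hal, which codes for histidine ammonia-lyase and lies near Lum, was higher by 4.04 ± 0.61, at a mean of 238 against 16.1 TPM (6 of 6 matched treatments, limma adjusted p = 0.00306). Lum, the targeted gene, was higher by 1.78 ± 0.31 in the libraries labelled as lacking it (6 of 6, limma adjusted p = 0.00689). Of 23 cholesterol synthesis genes, all were higher and 8 passed (16 adjusted over the list alone), with a median of 0.37, among them Sqle at 0.60 ± 0.11 and Hsd17b7 at 0.70 ± 0.12. Camera gave the list adjusted p = 7.57e-17, but adjusted p = 0.178 with an estimated correlation. Of 14 oxidative stress genes, 0 were higher and 6 lower (0 and 11 adjusted over the list alone), with Nqo1 at -0.74 ± 0.08, Gsta3 at -1.02 ± 0.14 and Srxn1 at -0.52 ± 0.10. As a set, they had a camera adjusted p = 1.68e-07, but adjusted p = 0.199 with an estimated correlation.

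The chemokine gene Ccl12 was higher by 1.99, Slfn4 by 1.66, the Fc receptor gene Fcgr4 by 1.46, the endocytic adaptor gene Dab2 by 1.29, the coagulation factor gene F13a1 by 1.27 and the calcium channel gene Cacna1d by 1.25. Lower were the mast cell chymase gene Cma1 (-2.62), Tph1, which makes serotonin (-1.95), the protease inhibitor genes Cst7 (-1.22) and Serpinb1a (-1.03), Slc16a9 (-1.20), Artn (-1.15), Susd2 (-1.10) and the glutathione transferase gene Gstm2 (-1.02). Of 21 scavenger and phagocytic receptors, 8 were higher and 3 lower (13 and 4 adjusted over the list alone), with the complement gene C1qc at 1.24 and Marco at -0.47. Taken as a list, they had a camera adjusted p = 3.13e-06, but adjusted p = 0.178 with an estimated correlation. Of 10 alternative activation genes, 2 were higher (5 adjusted over the list alone), with the folate receptor gene Folr2 at 1.03. Tested together with camera, they had adjusted p = 0.00151, but adjusted p = 0.178 with an estimated correlation. Interferon-stimulated genes had a median of 0.60, with 37 of 39 higher, but 1 passed up and 1 down (2 and 1 adjusted over the list alone; camera adjusted p = 7.94e-11, but adjusted p = 0.316 with an estimated correlation). Oxidative phosphorylation genes had 0 up and 3 down of 24 (0 and 10 adjusted over the list alone; camera adjusted p = 3.94e-05, but adjusted p = 0.199 with an estimated correlation). Other counts up and down, with those adjusted over the list alone in brackets, were 1 and 6 for endocytic genes (2 and 9), 3 and 0 for NF-kB genes (3 and 0), 3 and 1 for glycolysis (3 and 1), 1 and 0 for cytokines (0 and 0), 2 and 2 for LXR targets (2 and 2), 2 and 0 for matrix genes (5 and 1), 0 and 1 for the unfolded protein response (0 and 2), 0 and 1 for heat shock (0 and 4), and 0 and 0 for antigen presentation and the cell cycle. After scaling, counts up and down were 10 and 0 for cholesterol synthesis, 0 and 5 for oxidative stress, 8 and 2 for scavenger receptors, 2 and 0 for alternative activation, 2 and 0 for interferon-stimulated genes, 0 and 1 for oxidative phosphorylation, 1 and 3 for endocytic genes and 0 and 0 for heat shock. In all, 15 of 22 lists passed camera for this label, and 0 with an estimated correlation. Among TLR genes, Cd14 alone passed, at 0.40 ± 0.09, whereas Tlr4 was 0.19 ± 0.10 and Tlr9 -0.03 ± 0.17. In all, limma called 627 genes, 193 up and 434 down, and 247 up and 280 down after scaling. Leaving out the CpG libraries gave 10 genes, the LPS libraries 43 and the unstimulated ones 1268; without the 2 libraries that differ by less than noise the count was 1219, and with a mast cell score in the fit 189.

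Libraries labelled Bgn-/- differed from wild type in few genes, led by mast cell genes. The tryptase gene Tpsab1 was at a log2 of -3.19 ± 0.38 and Tph1 at -2.04 ± 0.27 (6 of 6 matched treatments, limma adjusted p = 0.00236 and 0.00485). Of 8 mast cell genes, 4 were lower (7 adjusted over the list alone), with a median of -2.31. For this list, camera gave adjusted p = 3.08e-16, and adjusted p = 0.0491 with an estimated correlation. The lower level is not particular to this label. For Cpa3, Cma1, Tpsab1, Tpsb2 and Mcpt4, every library of both knockout labels lay below every wild-type library except the untreated one, which was low too. For Kit, Slc18a2 and Hdc, the knockout libraries overlapped those wild-type libraries. The resistin-like gene Retnla, a marker of alternative activation, was at -1.15 ± 0.14, and the proliferation marker gene Mki67 at -0.63 ± 0.09. Higher were Apol7c (0.88), the calcium-binding protein gene S100a4 (0.87), the lysyl oxidase gene Loxl2 (0.79), the tight junction gene Tjp1 (0.66), Sipa1l1 (0.45) and the annexin gene Anxa1 (0.42). Lower were Cst7 (-0.92) and Serf1 (-0.70). Immunoglobulin variable genes went both ways, with Igkv6-32 at 1.61, Igkv12-44 at 1.40, Igkv4-91 at -1.34 and Ighv12-3 at -1.19; reads of such related genes are uncertain. Among the pathway lists, the 1 alternative activation gene and the 1 cell cycle gene that passed are Retnla and Mki67, and 0 members of the rest passed (adjusted over the list alone, 1 up and 3 down for endocytic genes, 0 and 3 for scavenger receptors and 2 and 1 for LXR targets). Cytokines leaned down (19 of 25 lower, camera adjusted p = 0.000178, but adjusted p = 0.554 with an estimated correlation), as did interferon-stimulated genes (36 of 39 lower, camera adjusted p = 0.00182, but adjusted p = 0.734 with an estimated correlation), scavenger receptors (16 of 21 lower, camera adjusted p = 0.00169, but adjusted p = 0.554 with an estimated correlation), NF-kB genes (15 of 20 lower, camera adjusted p = 0.0144, but adjusted p = 0.557 with an estimated correlation) and antigen presentation (14 of 19 lower, camera adjusted p = 0.0144, but adjusted p = 0.557 with an estimated correlation). Heat shock genes leaned up (9 of 9 higher, camera adjusted p = 0.0177, but adjusted p = 0.554 with an estimated correlation). Lum was -0.27 ± 0.31, Tlr4 0.18 ± 0.10, Tlr9 -0.01 ± 0.17 and Cd14 0.17 ± 0.09, none past the test. In all, limma called 25 genes, 10 up and 15 down, and 114 without the 2 libraries. Leaving out the LPS libraries gave 0, the CpG libraries 1 and the unstimulated ones 169.

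Added protein changed few single genes. Each comparison of a protein with a stimulus also uses the library with that stimulus alone under the label not given the protein, so its values can differ from those of the matched pairs. With lumican and LPS against LPS alone, the potassium channel subunit gene Kcnab2 rose by 0.82 ± 0.10, the autophagy gene Gabarapl1 by 0.70 ± 0.11 and the cilium transport gene Ift57 by 0.55 ± 0.08, and the GTPase gene Rab29 changed by -0.55 ± 0.08 (both genotypes, limma adjusted p of 0.0319 to 0.0457). These 4 were all the genes called, out of 1612 at unadjusted p under 0.05. All 39 interferon-stimulated genes were lower with lumican and LPS, with a median of -0.37 and 0 passing, also adjusted over the list alone. The list's camera test gave adjusted p = 7.57e-10, but adjusted p = 0.528 with an estimated correlation. Other lists leaned down with 0 passing, namely antigen presentation (18 of 19 lower; camera adjusted p = 5.2e-07, but adjusted p = 0.355 with an estimated correlation), cytokines (16 of 25; camera adjusted p = 0.00174, but adjusted p = 0.528 with an estimated correlation), scavenger receptors (15 of 21; camera adjusted p = 0.000606, but adjusted p = 0.355 with an estimated correlation) and heat shock (6 of 9, with 3 down adjusted over the list alone; camera adjusted p = 0.0012, but adjusted p = 0.355 with an estimated correlation). NF-kB genes (11 of 20 lower; camera adjusted p = 0.0135, but adjusted p = 0.56 with an estimated correlation), alternative activation (8 of 10; camera adjusted p = 0.0257, but adjusted p = 0.371 with an estimated correlation) and large peritoneal macrophage genes (9 of 14; camera adjusted p = 0.0248, but adjusted p = 0.528 with an estimated correlation) did too. Cxcl10 was -1.31 ± 0.41 (limma adjusted p = 0.189, both genotypes), and the cytokine gene Il12b 0.95 ± 0.27. All 14 oxidative stress genes were higher with lumican and LPS, with a median of 0.24 and 0 passing (1 adjusted over the list alone), with Me1, which supplies NADPH, at 0.55 ± 0.10 (limma adjusted p = 0.0626; camera adjusted p = 0.0248, but adjusted p = 0.647 with an estimated correlation). After scaling, that median was 0.11. With biglycan and LPS, all 14 were higher too, with a median of 0.34 and 0 passing (1 adjusted over the list alone; camera adjusted p = 0.000709, but adjusted p = 0.537 with an estimated correlation), and the median was 0.20 after scaling. With biglycan and CpG, all 39 interferon-stimulated genes were lower, with a median of -0.70 and 0 passing, also adjusted over the list alone, Ifit1 at -1.13 ± 0.64 and Ifit2 at -1.32 ± 0.82. Camera gave the list adjusted p = 2.03e-22, but adjusted p = 0.438 with an estimated correlation. That fit also uses the CpG library labelled Lum-/-, which has no biglycan partner. In the matched pairs of single libraries, the median was -1.06 in wild type and -0.00 under the label Bgn-/-, so of these pairs the wild-type one carried the fall. With 1 pair per genotype, these medians do not test a difference between genotypes. With lumican and CpG, 20 of 25 cytokine genes were higher, with a median of 0.30 and 0 passing, also adjusted over the list alone. As a set, they had a camera adjusted p = 5.43e-05, but adjusted p = 0.671 with an estimated correlation.

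Counts for the other protein comparisons were 0 in limma. Of 22 lists, camera passed 7 for lumican over all stimuli, 7 for biglycan over all stimuli, 9 for lumican with LPS, 5 for lumican with CpG, 10 for biglycan with LPS and 6 for biglycan with CpG, and 0 in each with an estimated correlation. At unadjusted p under 0.05, limma gave 1218 genes for lumican over all stimuli, 1055 for biglycan over all stimuli, 218 for lumican with CpG, 1340 for biglycan with LPS and 365 for biglycan with CpG. For lumican with LPS, the median of all genes was 0.10, which scaling moved to -0.02, with 3 genes up and 17 down; for biglycan with LPS it was 0.10 and -0.02, with 0 up and 1 down. Without the 2 libraries, lumican with LPS gave 265 genes and biglycan with LPS 20, and leaving out any of the 4 libraries compared gave 0 for lumican with LPS.

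Differences between genotypes in the response were tested as such, and limma called 0 genes in each of the 6 comparisons. Of 22 lists, camera passed 6 for LPS and 4 for CpG under the label Lum-/-, 9 for LPS and 8 for CpG under the label Bgn-/-, 3 for lumican and 8 for biglycan, and with an estimated correlation 1, for CpG under the label Bgn-/-. At unadjusted p under 0.05, limma gave 1445 genes for LPS and 821 for CpG under the label Lum-/-, 558 for LPS and 626 for CpG under the label Bgn-/-, 327 for lumican and 487 for biglycan. The response of cytokine genes to CpG was smaller under the label Bgn-/- than in wild type, by a median of -0.90 over 25 genes, with 0 passing (0 up and 12 down adjusted over the list alone; camera adjusted p = 5.37e-20, and adjusted p = 0.0219 with an estimated correlation). That comparison uses the wild-type untreated library, which stands apart, and the biglycan-alone library labelled Bgn-/-, and without the 2 libraries its median was -0.86. The medians of CpG against untreated in single libraries, 0.81 in wild type and 0.35 under the label Bgn-/-, differ by less. Nos2, the inducible nitric oxide synthase gene, differed by -2.13 ± 0.24 (limma adjusted p = 0.124) and Il1b by -1.87 ± 0.38 (limma adjusted p = 0.612). Nos2 was at 31.3 TPM with CpG in wild type and at 10.6 under the label Bgn-/-, from 4.10 and 9.79 untreated. In the same comparison, 38 of 39 interferon-stimulated genes were lower, with a median of -1.11. Taken as a list, they had a camera adjusted p = 3.61e-21, but adjusted p = 0.408 with an estimated correlation, and without the 2 libraries their median was -0.42. The effect of biglycan on interferon-stimulated genes was higher under the label Bgn-/- for 38 of 39, with a median of 0.97 (camera adjusted p = 5.61e-19, but adjusted p = 0.339 with an estimated correlation), and that comparison uses the biglycan-alone library. After LPS, interferon-stimulated genes differed by a median of -1.19 under the label Lum-/- (camera adjusted p = 1.05e-06, but adjusted p = 0.753 with an estimated correlation), and all 14 oxidative stress genes were higher under the label Bgn-/- (6 adjusted over the list alone; camera adjusted p = 3.65e-07, but adjusted p = 0.304 with an estimated correlation). The first of these is measured in part from the untreated library labelled Lum-/-, 1 of the 2 libraries, and from the wild-type untreated library, and without the 2 libraries its median was -0.65; the second uses the biglycan-alone library. For the response to LPS under the label Lum-/-, the median of all genes was -0.12, and 0.03 after scaling. With the untreated library labelled Bgn-/- left out, the unstimulated arm of that label is the biglycan-alone library, 1 of the 2 libraries. With either lumican-alone library left out, the unstimulated arm of the label Lum-/- rests on its untreated library, the other of the 2. Counts of genes from these fits are therefore not read as differences between genotypes.

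Markers of cell types were read per library and by camera. Large peritoneal macrophage genes fell with LPS in 12 of 14 (1 up; after scaling 4 up and 6 down), with the lineage factor gene Gata6 down at -1.41 and Vsig4 at -2.01, and with CpG in 6 of 14 (0 up; 8 adjusted over the list alone, and 4 after scaling), with Gata6 down at -0.69. The camera test of that list did not pass for LPS (adjusted p = 0.955), and passed for CpG (adjusted p = 0.0317, but adjusted p = 0.521 with an estimated correlation). Alox15, on that list and on the eosinophil list, fell with LPS, and 1 of 2 eosinophil genes thus passed. Of 7 genes of small macrophages, monocytes and dendritic cells, 0 rose and 3 fell with LPS (0 and 2 adjusted over the list alone, and 3 and 1 after scaling), with Clec9a down at -2.40. Of 17 B cell genes, 0 rose and 6 fell with LPS (0 and 4 adjusted over the list alone, and 7 and 2 after scaling), and 1 rose and 5 fell with CpG (2 and 5 adjusted over the list alone), with Ms4a1 down at -1.37. Of 6 T and NK cell genes, 1 rose and 2 fell with LPS (3 and 0 after scaling), and 1 rose and 1 fell with CpG, with Cd2 down at -1.84. Of 4 neutrophil genes, 2 rose and 1 fell with LPS (3 and 1 after scaling), with S100a8 up by 1.30, and 2 rose and 2 fell with CpG. Of the other lists with few tested genes, the 1 mesothelial and fibroblast gene, Pdgfrb, rose with LPS by 1.91, the 2 platelet genes, Pf4 and Ppbp, did not pass, and 4 of 4 Y-linked genes fell with LPS (1 after scaling) and 1 with CpG (4 adjusted over the list alone, and 0 after scaling). No erythroid gene reached a mean of 1 TPM. Under the label Lum-/-, mast cell genes were lower in 4 of 8 (6 adjusted over the list alone), with Tpsb2 at -2.53 ± 0.51 (camera adjusted p = 4.33e-05, but adjusted p = 0.199 with an estimated correlation), and 1 of 8, the histamine-forming enzyme gene Hdc, rose with LPS by 5.32 ± 0.60 (4 after scaling). Mast cell genes were higher in 7 of 8 with LPS (camera adjusted p = 0.000981, but adjusted p = 0.284 with an estimated correlation) and in 8 of 8 with CpG, with a median of 0.87 and 0 passing (camera adjusted p = 0.0317, but adjusted p = 0.521 with an estimated correlation), against untreated libraries that include the wild-type library low in them. Between genotypes, large peritoneal macrophage genes had 3 up and 1 down under the label Lum-/-, with Timd4 at -0.90, and B cell genes 0 up and 2 down (0 and 3 adjusted over the list alone, and 0 and 1 after scaling), with Bhlhe41 at -0.57. All 17 B cell genes were lower under that label, with a median of -0.19 (camera adjusted p = 0.0135, but adjusted p = 0.553 with an estimated correlation), and without the 2 libraries 10 fell, with a median of -0.38.

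Between single libraries, the lists moved as follows, as a description of those libraries. Values against untreated in wild type and under the label Lum-/-, and values of the untreated pair, use untreated libraries that stand apart. Interferon-stimulated genes rose with LPS by a median of 3.42 in wild type, 1.97 under the label Lum-/- and 3.86 under the label Bgn-/-, above all random lists in each. With CpG, their median was 1.28, 0.35 and 0.26. Cxcl10 was at 62.1 TPM with CpG in wild type, 79.3 under the label Lum-/- and 13.6 under the label Bgn-/-, from 9.48, 23.1 and 7.35 untreated. Cytokine genes had medians of 0.81, 0.81 and 0.35 with CpG, and 5.64, 5.78 and 5.45 with LPS. Cholesterol synthesis genes rose with CpG by 1.46, 1.40 and 0.69, and were higher under the label Lum-/- than in wild type in all 6 matched treatments, by 0.31 to 0.55. Mast cell genes were lower under that label in 5 treatments, with medians of -1.95 to -2.89, and higher in the untreated pair, at 0.66. Of 572 planned lists, 292 lay outside the central 95% of random lists, 148 above and 144 below.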

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

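The counts without the 2 libraries, and the tests of explanations, were chosen only after the results were seen. The response to LPS differed between the label Bgn-/- and wild type in 212 genes, and the response to CpG in 237, when the untreated library labelled Lum-/- and the biglycan-alone library labelled Bgn-/- were left out. A test of the difference between 2 groups' responses picked them out, since limma called 0 genes in both with all 21 libraries, with 558 and 626 at unadjusted p under 0.05. Without those libraries, the unstimulated arm of each difference rests on a single pair, the untreated library labelled Bgn-/- and the wild-type untreated library, since the wild-type biglycan-alone library is then alone in its treatment. Leaving out the biglycan-alone library by itself, with the same single pair, gave 4 and 18, so the counts depend on leaving out the untreated library labelled Lum-/- as well. The wild-type untreated library stands apart from the other wild-type libraries, and without it the differences were not fitted.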

How the results depend on the processing

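The settings added after the data were seen are those without the 2 or the 3 libraries, coding genes only, the mast cell score, the mean over protein levels, and the list tests after scaling or without the 2 libraries; the cause of each change was not tested. With only the libraries compared, limma called 0 genes for CpG, 362 for Lum-/-, 7 for Bgn-/-, 48 for lumican, 0 for lumican with LPS and 7 for lumican with CpG. With no filter it called 336 for Lum-/-, 3 for lumican, 1 for biglycan, 20 for lumican with LPS, 5 for lumican with CpG, 6 for biglycan with LPS, 4 for biglycan with CpG and 1 for the biglycan effect in Bgn-/-. Without the 2 libraries, the counts were 1219 for Lum-/-, 114 for Bgn-/-, 1 for biglycan, 265 for lumican with LPS, 20 for biglycan with LPS, and 212 and 237 for the LPS and CpG responses in Bgn-/-. Without the 3, they were 926 for CpG, 1447 for Lum-/-, 183 for Bgn-/-, 336 for lumican with LPS, 1 for lumican with CpG, 24 for biglycan with LPS, and 1 each for the LPS and CpG responses in Lum-/-, and a mean over protein levels gave 4466 for CpG. A mast cell score gave 189 for Lum-/-. Lumican with LPS gave 41 with a pseudocount of 0.1, 1 with a pseudocount of 5, 22 at 5 TPM or more, 20 after median-of-ratios scaling, 1 after quantile normalization, 0 with the most abundant transcript and 1 with coding genes. Biglycan with LPS gave 1 after either normalization, the LPS response in Lum-/- 2 with a pseudocount of 5, and the CpG response in Bgn-/- 1 with the most abundant transcript. List tests past the threshold were 139 of 374 with the preset correlation and 8 with an estimated correlation, 128 after scaling and 169 without the 2 libraries. Leaving out libraries or treatments in turn, counts ranged over 8298 to 9102 for LPS, 0 to 1776 for CpG, 7962 to 8662 for LPS against CpG, 10 to 1268 for Lum-/-, 0 to 169 for Bgn-/-, 0 to 11 for lumican, 0 to 6 for biglycan, 0 to 0 for lumican with LPS, 0 to 1 for lumican with CpG, 0 to 1 for biglycan with LPS, 0 to 770 and 0 to 540 for the LPS and CpG responses in Lum-/-, and 0 to 46 and 0 to 108 for those in Bgn-/-. For LPS, CpG and LPS against CpG, all libraries of a genotype were left out in turn. In these ranges, the highest counts for the LPS and CpG responses come from fits whose unstimulated knockout arm is 1 of the 2 libraries. A lone library left in an arm is assumed to vary like the others. Robust eBayes kept 17 of 17 counts within 1.5 times, and leaving out the genotype block 3 of 3. Of 572 single-library lists, 292 lay outside the random range, 291 with a pseudocount of 0.1, 289 after scaling and 273 of 520 at 5 TPM or more. The LPS and CpG responses in Bgn-/- could not be fitted without the 3 libraries. No analysis paired by animal was possible because no label ties a well to an animal.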

Other observations

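The tests of explanations and the splits below were chosen only after the results were seen.

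In single libraries, interferon-stimulated genes were lower with added protein and stimulus than with the stimulus alone in wild type, by a median of -0.40 with lumican and LPS, -0.39 with biglycan and LPS, -0.23 with lumican and CpG and -1.06 with biglycan and CpG, and under the label Lum-/- by -0.10 with lumican and LPS and -0.35 with lumican and CpG. Cxcl10 in wild type went from 3710.1 TPM with LPS to 1318 with lumican and 1644 with biglycan, and from 62.1 with CpG to 30.7 and 20.5. In wild type, lumican and biglycan were compared with the same LPS-alone library and with the same CpG-alone library. These falls are therefore not independent, and a high value in a shared library would give both. Under the label Bgn-/-, the medians with biglycan were -0.03 with LPS and -0.00 with CpG, but limma called 0 genes for the difference from wild type, with 487 at unadjusted p under 0.05. In the fit of all libraries, lumican with CpG had a median of 0.09, with 34 of 39 higher (camera adjusted p = 0.364, and not passing with an estimated correlation either). That fit also uses the CpG library labelled Bgn-/-, which has no lumican partner, so its sign is not that of the matched pairs, both of which were lower. Oxidative stress genes were higher in 14 of 14 with lumican and LPS in wild type (0.28) and under the label Lum-/- (0.39), and with biglycan and LPS under the label Bgn-/- (0.24). The wild-type pair with biglycan and LPS is not among those given. These values are unscaled. In the fit of all libraries, scaling lowered the list's median to 0.11 for lumican with LPS and 0.20 for biglycan with LPS. They are also single libraries, so a repeat with replicate wells is the test.

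The untreated library labelled Lum-/- and the biglycan-alone library labelled Bgn-/- had a noise ratio of 0.1895. In simulated data, 2 draws from the recovered reads of 1 library, which can share reads, gave 0.8225 to 0.925. The pair differed by less than such draws. Much the same reads may therefore stand under both labels, rather than separate samplings of shared material. The columns are not identical, with Bgn at 1.72 and 0 TPM. Low depth alone is argued against by 87 genes over 2-fold outside the range of all other libraries, against at most 28 in libraries thinned to the same depth. Cells of the label Bgn-/- are argued against by a position of 0.3831 between the labels Lum-/- (0) and Bgn-/- (1), where the other libraries labelled Bgn-/- lay at 0.6676 to 0.9682, and by Hal at 183 TPM, against at most 2.59 in them. Of 5 genes that part those labels elsewhere, 4 reached the level of the label Lum-/- in both libraries and 1 lay between the labels. Hal, at 182 and 183 TPM, lay above every wild-type library (at most 28.6). The untreated library labelled Lum-/- was also off its own label, at 0.6225 between the labels Bgn-/- (0) and Lum-/- (1). The other libraries labelled Lum-/- lay at 0.8062 to 1.001, but the untreated library labelled Bgn-/- lay at 0.6676 towards its own label, about as far off. For the pair, the untreated level came from that library and the wild-type untreated one. The biglycan-alone level came from the wild-type library only. These positions therefore do not show by themselves that the pair lies between the labels. The values under the label Bgn-/- are thus not those of cells of that label alone, but the labels give the libraries different RNA purity and fragment size, and how the values came to stand under both stays open.

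Without the 2 libraries, Lum was higher under the label Lum-/- than under Bgn-/-, and Bgn the other way round, so exchanged labels are a candidate explanation. Without them, genes called for the label Lum-/- were enriched within 5 Mb of Lum, 8 of 31 against 3.21 by chance (one-sided Fisher's exact adjusted p = 0.0464), but with all libraries they were 4 of 31 against 1.65 (one-sided Fisher's exact adjusted p = 0.32). Hal, which lies near Lum, was also called for the label Bgn-/- without the 2 libraries, at -2.57, as an exchange would allow. Near Bgn, without the 2 libraries, 5 of 61 genes were called for the label Lum-/- against 6.31 by chance (one-sided Fisher's exact adjusted p = 0.77), where an exchange predicts enrichment. For the label Bgn-/-, where correct labels predict it, 1 of 61 was called against 0.591 (one-sided Fisher's exact adjusted p = 0.597). With a stimulus, Lum in wild type was at 8.25% to 10.3% of the matched libraries labelled Lum-/-, which an exchange alone leaves unexplained. Exchanged and correct labels therefore cannot be told apart. Transcripts from a disrupted gene, other strain sequence near Lum and a biological explanation were not tested.

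The wild-type untreated library had fewer mast cell transcripts than the other 8 wild-type libraries. Fewer mast cells and no other difference is argued against by 25 further genes over 2-fold outside the range of the others, against at most 7 in any other of the 19 libraries left after the pair above was set aside; Alox15 (1168 TPM) was among those above. Cells of the label Lum-/- are argued against by Hal at 4.44 TPM, against at least 88.2 in the libraries of that label. Cells of the label Bgn-/- and of wild type cannot be told apart in this library: of the 3 genes that part those labels in all other libraries, 2 had the level of wild type and 1 that of the label Bgn-/-, and the position of 0.3855 rests on a single pair. For CpG, limma called 2295 genes without the 2 libraries and 926 without this library as well, and for LPS 9669 and 9080.

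For the 627 genes of the label Lum-/-, 1 of 100 splits of the wells gave as many, the division as labelled (highest other 6). Of the 32 splits that exchange labels only within matched treatments, 1 did, again the division as labelled (highest other 2). A random division of these wells is thus argued against. The splits exchange wells, and a genotype and its cell preparation are confounded, so they cannot exclude a difference between preparations. For the 25 of the label Bgn-/-, 2 of 100 splits gave as many, but 2 of the 32 matched splits did too, so chance cannot be excluded where treatments stay matched (highest other 27, with the biglycan-alone pair exchanged). Among the 100, the highest other called 611. It put both untreated libraries, the wild-type biglycan libraries and the library labelled Bgn-/- with biglycan and LPS on the same side. What drives that count was not tested. The 10 splits for LPS (9513, highest other 0), CpG (2262, highest other 16) and LPS against CpG (9359, highest other 0) are too few for a share under 0.05, with 1 split each giving as many. For the 0 genes of lumican and of biglycan (limma, with 1218 and 1055 at unadjusted p under 0.05), all 87 of 87 splits give as many whatever the data, so the splits say nothing about chance. The highest others were 3 and 515, and what drives the 515 was not tested either.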
